A study of Homo sapiens with 496 samples.

How the data were processed

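The values were log2 signals per Affymetrix probe set as deposited by the authors. Total RNA had been labelled with the Affymetrix HT One-Cycle kit. How the arrays were scanned, summarised and normalized was not given in the sources used here. The quantiles of the arrays were nearly but not exactly equal, and no further scaling was applied here. The values ran from 2.69 to 14.36, the array medians from 5.03 to 5.44 and the array 75th percentiles from 7.92 to 8.14. No array was left out and 0 value columns were unused. No 2 arrays were identical.

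Work was done in R 4.3.3 with limma 3.58.1 and version 1.17.8 of the data.table package, and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Of 22277 probe sets, 62 control probe sets stayed out of the gene tests. The platform annotation gave exactly 1 gene symbol to 19064 probe sets, several symbols to 1043 and none to 2108. Probe sets with several symbols or none were not analysed here as genes, with the exception of the 3 probe sets shared by HSPA1A and HSPA1B, which were read as probe sets. A gene was represented by the probe set with the highest mean over all arrays among its probe sets with 1 symbol, which gave 11963 genes, of which 4310 had more than 1 probe set. Positions are on GRCh38 and were joined by gene ID for 19052 probe sets.

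The effect of a dose was the treated array minus the 0 nM array of the same cell line and time point. These differences were tested against 0 with limma's moderated test, with the line as the pair. Benjamini-Hochberg adjustment ran over all 11963 genes, and a gene was called at adjusted p below 0.05. The difference between doses was the 1000 nM array minus the 100 nM array of the same line, and the difference between time points was the effect at 1 time point minus the effect at the other. Tissues of origin were compared with limma's moderated F test on the 1000 nM effects. Each tissue with at least 4 lines was also set against the unweighted mean of the other tissues. The pairing of arrays by line was checked against the values. After the group means were taken off, the treated and 0 nM arrays of 1 line correlated at medians of 0.885 to 0.974, and those of different lines at -0.05 to -0.04.

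These tests, the gene lists and the rule for naming genes were fixed before the data were examined. For 1000 nM the rule took called genes that moved in the direction of the mean in at least 80% of lines, and of these the 12 largest rises and the 12 largest falls. It took 6 each way for 100 nM and for the differences between doses and time points, 5 each way for 0 nM over time, the 10 smallest p-values of the tissue test, and 4 each way for a single tissue. It took up to 4 members per list with the largest absolute mean difference. HSPA1A, HSPA1B, DNAJB1, HSPH1, HSP90AA1, HSP90AB1, HSPA5, HSF1, NQO1 and ABCB1 were named in any case. Genes named outside this rule are marked as chosen after the values were seen.

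The 27 gene lists were HSF1 chaperones, HSP90 co-chaperones, ER unfolded protein response, ATF4 integrated stress response, proteasome subunits, ubiquitin and autophagy, NRF2 targets, metallothioneins, MAPK pathway output, HSP90 client kinases and receptors, DNA replication and G1/S, G2/M and mitosis, p53 targets, cholesterol synthesis, hypoxia HIF targets, glucocorticoid receptor targets, NF-kB targets, interferon-stimulated genes, apoptosis regulators, histones, cytosolic ribosomal proteins, ribosome biogenesis, TGF-beta and extracellular matrix, epithelial markers, melanocyte markers, leukocyte markers, and neural and glial markers. They were written from general knowledge of the pathways. Some lists share members, so their calls are not independent. CHORDC1, STIP1, FKBP4, PTGES3 and CACYBP count both as HSF1 chaperones and as HSP90 co-chaperones. DDIT3 is in both the ER and the ATF4 list. PLK1, AURKB, CDK1 and BIRC5 are in both the client and the G2/M list. Each was tested with limma's camera test, which compares the members with all other genes, at a preset correlation between genes of 0.01 and again with an estimated correlation. The p-values of the 27 lists in the 6 comparisons of a dose with 0 nM were adjusted together. The camera test on the differences between doses and between time points and on 0 nM over time was added after the data were seen, and was adjusted as a family of its own. The fry test was run beside it and asks only for movement of the members in 1 direction. A list score of a line is the mean log2 difference over the measured members.

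Correlations were tested by permutation with 100000 draws, and small groups by an exact or drawn sign-flip permutation test. The chance check repeated each count with signs or tissue labels drawn at random, for 100 splits that included the real one.

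The code was tested on simulated data with 200 changed genes. At the spread seen at 24 h it recovered 15 of 50 genes shifted by 0.10, 34 of 50 shifted by 0.25 and 50 of 50 shifted by 0.50 or 1.00, and called 4 of 11763 unchanged genes. At the spread seen at 6 h it recovered 24 of 50 genes shifted by 0.10 and at 2 h 37 of 50, and all larger shifts. The tissue F test recovered 36 of 50 genes shifted by 1.00 in a random group of 9 lines, the size of the largest tissues, at 24 h and 49 of 50 at 6 h. Smaller tissues and the tests of single tissues were not simulated. The camera test recovered 2 of 2 shifted lists at each time point but also called 4, 4 and 2 of 25 unchanged lists at 24 h, 6 h and 2 h with the preset correlation, which is why each list call is given with the estimated correlation too.

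The alternatives tried were no pairing by line, the Wilcoxon signed-rank or Kruskal-Wallis test in place of limma, array weights, an adjusted p below 0.01, the mean of all probe sets of a gene, dim genes left out, each array centred on its median, quantile normalization, lines with all 9 arrays only, each tissue left out in turn, tissues with fewer than 4 lines left out, and 3 lines that share their source with other lines of the panel left out, which were NCI-ADR-RES with OVCAR-8, SNB-19 with U251 and MDA-MB-435 with M14. Each line was hybridised once per dose and time point, so differences between 2 single lines are not told from differences between arrays.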

Results

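The data were collected to compare, over time, the transcriptional responses of the NCI-60 panel of human tumour cell lines to anticancer agents. The agent here was geldanamycin, which blocks the ATP site of the chaperone HSP90. The 496 arrays covered 57 lines from 9 tissues of origin at 0, 100 and 1000 nM and at 2, 6 and 24 h. There were 9 melanoma, 9 lung, 7 colon, 7 ovarian, 7 renal, 6 breast, 6 CNS, 4 leukemia and 2 prostate lines. Each line gave 1 array per dose and time point, and 50 lines had all 9 arrays. At 2 h there were 52 lines per dose and no leukemia line. At 6 h there were 57 arrays at 0 nM and 56 at each other dose, and at 24 h there were 57 at each dose. Expression is given as log2 signal, differences are paired by line, and ± is the standard error of the mean difference unless SD is stated. Adjusted p-values of genes come from limma's moderated test over 11963 genes.

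Which genes did 1000 nM change after 24 h? The largest rise was that of CLU (chr8 27596917-27614700), the gene of the secreted chaperone clusterin, at 1.87 ± 0.12 in 56 of 57 lines (adjusted p = 4.99e-20), or 3.65-fold. The HSP40 gene DNAJB4 (chr1 77979175-78017964) rose by 1.73 ± 0.09 in 57 of 57 lines (adjusted p = 2.76e-25), and HSPA4L, an HSP110 relative, rose by 1.37 ± 0.11 in 56. HSPH1, the gene of HSP110, rose by 1.03 ± 0.05 in 57 lines and DNAJB1 (chr19 14514769-14560391), an HSP40 gene, by 0.99 ± 0.07 in 55. The genes of the drug target itself rose less, HSP90AB1 by 0.53 ± 0.02 and HSP90AA1 by 0.32 ± 0.02, each in 57 of 57 lines. HSPA1A and HSPA1B, the inducible HSP70 genes, share 3 probe sets, 1 of them with HSPA1L too, and these rose by 1.47 ± 0.13 in 53 lines, 2.06 ± 0.09 in 57 and 2.33 ± 0.10 in 57. CCNG2, a cyclin of resting cells, rose by 1.73 ± 0.14 in 55 lines. The histone gene H2AC6 rose by 1.45 ± 0.17 in 49 lines, the prolyl hydroxylase gene P4HA2 by 1.42 ± 0.11 in 56, and the regulator of G-protein signalling RGS2 by 1.57 ± 0.22 in 48. Of the further genes with the largest rises, DHRS2 rose by 1.71 ± 0.24, RSRP1 by 1.58 ± 0.07, FAM13A by 1.34 ± 0.12, TMT1A by 1.34 ± 0.16 and YPEL5 by 1.25 ± 0.14. The drug efflux pump gene ABCB1 rose by 0.36 ± 0.10 in 36 of 57 lines (adjusted p = 0.00123). In most lines its 0 nM level lay below every array median, so the size of this rise is uncertain.

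CCNE2 (chr8 94880224-94896693), the gene of the S-phase cyclin E2, fell by 2.999 ± 0.19 in 55 of 57 lines (adjusted p = 1.87e-20). Other replication genes went the same way. CDC45 (chr22 19479466-19520612) fell by 2.28 ± 0.11 in 57 lines, MCM10 by 2.25 ± 0.15 in 56 and the primase gene PRIM1 by 2.04 ± 0.10 in 57. Genes that ERK signalling switches on fell as well. The phosphatase gene DUSP6 (chr12 89347235-89352501) fell by 2.53 ± 0.21 in 55 lines, FOSL1 (chr11 65892049-65900545) by 2.42 ± 0.19 in 55, ETV5 by 2.07 ± 0.18 in 54 and EGR1 by 2.07 ± 0.17 in 55. IER3 (chr6 30743199-30744547), an immediate early gene, fell by 2.66 ± 0.19 in 56 lines, and ID1, an inhibitor of differentiation, fell by 2.57 ± 0.21 in 55. MAFF fell by 2.39 ± 0.19 and the TWEAK receptor gene TNFRSF12A by 2.12 ± 0.15. The heat shock factor gene HSF1 fell by 0.26 ± 0.04 in 48 lines (adjusted p = 2.47e-08). The quinone reductase gene NQO1 fell by 0.18 ± 0.05 in 38 lines (adjusted p = 0.00145), and HSPA5, the ER chaperone BiP, by 0.18 ± 0.07 in 35 (adjusted p = 0.0176).

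Of the 27 gene lists 8 moved against all other genes after 24 h by the camera test with the preset correlation, and the HSF1 chaperones kept the call with an estimated one. Of the 22 HSF1 chaperones 21 rose and none fell, and all 22 rose when adjusted over the list alone. Their mean rise was 0.76, and the score was above 0 in 57 of 57 lines (adjusted p = 1.47e-16 with the preset and adjusted p = 0.00762 with an estimated correlation). HSPB1, the small chaperone HSP27, rose by 1.11 ± 0.10 and the co-chaperone gene BAG3 by 1.10 ± 0.08, and PTGES3 at 0.06 was not called. All 28 measured genes of DNA replication and G1/S fell, with a mean of -1.36 and a score below 0 in 56 of 57 lines (adjusted p = 2.18e-20, adjusted p = 0.0723 with an estimated correlation). Of the 20 genes of MAPK pathway output 19 fell and EPHA4 rose by 0.28, with a mean of -1.33 and a score below 0 in all 57 lines (adjusted p = 8.08e-09, adjusted p = 0.0632 with an estimated correlation). Of 16 genes of ribosome biogenesis 15 fell, among them RRP9 by 1.08 and NOP16 by 0.87, though another probe set of NOP16 rose by 0.09 (adjusted p = 2.9e-07, adjusted p = 0.23 with an estimated correlation). Of 10 genes of ubiquitin and autophagy 9 rose, among them GABARAPL1 by 0.97, WIPI1 by 0.83 and BNIP3L by 0.78 (adjusted p = 0.000904, adjusted p = 0.116 with an estimated correlation). Of 26 cytosolic ribosomal proteins 19 rose and 2 fell, or 19 and 3 when adjusted over the list alone, with RPS9 up by 0.14 (adjusted p = 0.0135, adjusted p = 0.585 with an estimated correlation). Of 21 ATF4 genes 11 fell and 3 rose, with CEBPG down by 1.06, TRIB3 by 0.98 and DDIT4 up by 1.02 (adjusted p = 0.0314, adjusted p = 0.549 with an estimated correlation). Of 17 NF-kB targets 10 fell and 1 rose, with CXCL8 down by 1.46, NFKBIA by 0.80 and TNFAIP3 by 0.79 (adjusted p = 0.0293, adjusted p = 0.518 with an estimated correlation).

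The other 19 lists were not called at 24 h, though single members moved. Of 20 ER unfolded protein response genes 13 rose and 3 fell, with SEL1L up by 0.87 and HSP90B1 by 0.69 but SDF2L1 down by 1.11 and MANF by 1.03 (adjusted p = 0.063). Of 14 HSP90 co-chaperones 8 rose and 5 fell, or 9 and 5 when adjusted over the list alone, with FKBP5 down by 0.87 and RUVBL1 by 0.70 (adjusted p = 0.243). Of 25 HSP90 client kinases and receptors 10 fell and 5 rose, with AURKB down by 0.89, CHEK1 by 0.71, CDK4 by 0.66 and AKT1 by 0.56 and with ERBB3 up by 0.41 (adjusted p = 0.193). Of 27 proteasome subunits 14 fell and 3 rose, with PSMC3 down by 0.36, and the list median of -0.06 became 0.04 when each array was centred (adjusted p = 0.0827). Of 31 G2/M and mitosis genes 8 rose and 8 fell, or 8 and 7 when adjusted over the list alone, with NEK2 up by 0.63 and CENPF by 0.56 (adjusted p = 0.965). Their median was -0.01 while the test statistic pointed up, and it was 0.09 with each array centred. Of 18 NRF2 targets 7 rose and 6 fell, with AKR1C3 up by 1.02 and GCLM down by 0.37 (adjusted p = 0.772). Of 7 metallothioneins 5 fell and 1 rose, with MT1X down by 0.54 and MT2A by 0.51 (adjusted p = 0.145). Of 16 p53 targets 8 fell and 2 rose, with PMAIP1 down by 0.75, PLK3 by 0.60 and BAX by 0.50 (adjusted p = 0.323). Of 19 apoptosis regulators 9 fell and 5 rose, with CASP9 up by 0.68 (adjusted p = 0.593).

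Of 13 cholesterol synthesis genes 4 rose and 2 fell, with HMGCS1 up by 0.57 and EBP down by 0.54 (adjusted p = 0.746). Of 22 hypoxia targets 10 fell and 6 rose, with NDRG1 up by 0.88 and HK2 down by 0.82 (adjusted p = 0.746), and their median of -0.08 was below 0 while the mean of 0.02 was above it. Of 10 histones 5 rose and 2 fell, with H2BC21 up by 1.05, H2BC5 by 0.87 and H2AX down by 0.89 (adjusted p = 0.349). Of 19 genes of TGF-beta and extracellular matrix 7 fell and 3 rose, with ID3 down by 1.71, SMAD7 by 1.23 and ACTA2 up by 0.41 (adjusted p = 0.353). Of 22 interferon-stimulated genes 5 rose and 4 fell, with IFIT1 up by 0.78, BST2 by 0.66 and OAS3 down by 0.70 (adjusted p = 0.91). Of 9 glucocorticoid receptor targets 3 fell and 2 rose (adjusted p = 0.563). Of 14 epithelial markers 8 rose and 2 fell, with CDH1 up by 0.72 and ELF3 by 0.63 (adjusted p = 0.356). Of 11 melanocyte markers 5 rose and 2 fell (adjusted p = 0.626), of 14 leukocyte markers 5 rose and 2 fell with a median of 0.03 and a mean below 0 (adjusted p = 0.742), and of 12 neural and glial markers 5 fell and 3 rose, with NES down by 0.77 and TUBB3 by 0.52 (adjusted p = 0.649). With each array centred, the medians of the hypoxia targets and of the neural and glial markers became 0.01 and 0.06. PTGES3, EPHA4, ERBB3, GCLM and ACTA2, and ETV5 and SLBP at 6 h, were named after their values were seen. None of the 58 list calls in the 6 comparisons of a dose with 0 nM changed the sign of its median or mean with either other scaling. With an estimated correlation 21 of the 58 calls, some of them of lists that share members, held. These were the HSF1 chaperones in all 6 comparisons, the HSP90 co-chaperones at 6 h at both doses and at 2 h at 100 nM, the ER list at 2 h at both doses and at 6 h at 1000 nM, the ATF4 and G2/M lists at 2 h at both doses, ubiquitin and autophagy at 6 h at both doses, NRF2 targets at 6 h and cholesterol synthesis at 2 h at 1000 nM, and MAPK output at 6 h at 100 nM. The fry test, which asks only whether a list moves 1 way, ended 1, that of the epithelial markers at 100 nM and 2 h.

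At 24 h 1000 nM called 6796 genes, 3484 up and 3312 down, of which 42 rose and 174 fell at least 2-fold. Without pairing by line, 2932 genes were called. The median of all genes on an array was 0.10 lower at 1000 nM, while the median of the mean differences of single genes was 0.015. With each array centred on its median 6973 genes were up and 2374 down.

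**Figure D1:**
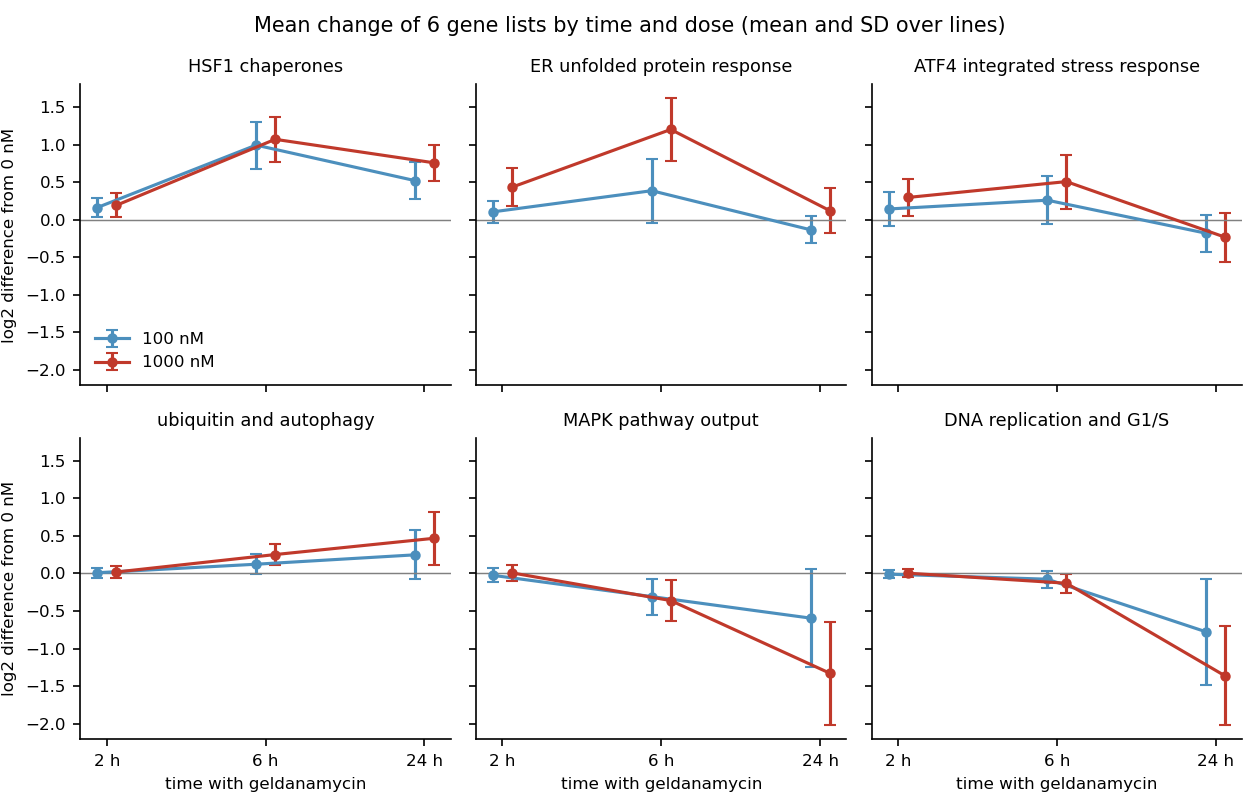
Mean score of 6 gene lists over lines (treated minus 0 nM, log2) against time in h, for 100 nM (blue) and 1000 nM (red), with bars of SD over lines. The mean ER score at 6 h was 0.39 at 100 nM and 1.20 at 1000 nM, while the mean replication score at 24 h was -0.78 and -1.36.

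What had 1000 nM changed by 6 h? The heat shock gene HSPA6 (chr1 161524540-161526894), which is nearly silent in unstressed cells, rose by 4.28 ± 0.31 in 54 of 56 lines (adjusted p = 2.56e-18), from a 0 nM mean of 4.08 that lay below every array median, so that its fold is not given. DNAJB1 rose by 2.50 ± 0.07 in 56 of 56 lines (adjusted p = 2.08e-38), BAG3 by 2.35 ± 0.09, DNAJB4 by 2.23 ± 0.09 and HSPH1 by 1.503 ± 0.055, each in 56 lines. The 3 probe sets of HSPA1A and HSPA1B rose by 2.50 ± 0.19, 3.25 ± 0.11 and 3.93 ± 0.12, each in 56 lines. Genes of the ER stress response rose beside them. HERPUD1 (chr16 56932142-56944864), a gene of ER-associated degradation, rose by 2.62 ± 0.12 in 56 lines (adjusted p = 7.15e-27). SDF2L1 rose by 2.27 ± 0.10 in 56 lines, DNAJB9 by 2.06 ± 0.14 in 52, the death-linked factor DDIT3 by 1.82 ± 0.10 in 56, SEL1L by 1.59 ± 0.08 in 55, DNAJC3 by 1.48 ± 0.08 in 55, MANF by 1.45 ± 0.07 in 56 and HSPA5 by 1.02 ± 0.05 in 56. HSP90AB1 rose by 0.37 ± 0.02, HSP90AA1 by 0.26 ± 0.02 and ABCB1 by 0.11 ± 0.04 (adjusted p = 0.0351). HSF1 fell by 0.17 ± 0.03 (adjusted p = 3.5e-05), and NQO1 at -0.03 was not called (adjusted p = 0.1).

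The falls at 6 h included targets of several signalling pathways. CYP1B1, a target of the aryl hydrocarbon receptor, fell by 1.35 ± 0.13 in 53 of 56 lines, and TIPARP, a second such target, by 0.82 ± 0.08 in 50. The fall of CYP1B1 was not called without pairing by line. IER3 fell by 1.33 ± 0.09 in 54 lines (adjusted p = 1.26e-19), JUNB by 0.90 ± 0.06 in 55 and IER2 by 0.90 ± 0.06 in 56. HES1, a Notch target, fell by 1.00 ± 0.07 in 55 lines, the homeobox gene DLX2 by 1.20 ± 0.13 in 53, ID1 by 0.90 ± 0.07 in 54 and SMAD7 by 0.88 ± 0.06 in 54. RHOB fell by 0.75 ± 0.07 and KLF10 by 0.70 ± 0.07. PCGF3 fell by 0.80 ± 0.06 in 56 lines on its brightest probe set, while another of its probe sets rose by 0.09 (adjusted p = 0.0199).

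All 20 measured ER unfolded protein response genes rose at 6 h with a mean of 1.20 (adjusted p = 2.62e-39, adjusted p = 0.00108 with an estimated correlation), and all 22 HSF1 chaperones rose with a mean of 1.07 and a score above 0 in 55 of 56 lines (adjusted p = 1.4e-41, adjusted p = 7.68e-05 with an estimated correlation). Of 21 ATF4 genes 18 rose, among them SLC7A11 by 1.34, DDIT4 by 1.11 and ASNS by 0.89 (adjusted p = 1.22e-14, adjusted p = 0.0603 with an estimated correlation). HSP90 co-chaperones had 7 members up and 4 down (adjusted p = 2.44e-05, adjusted p = 0.0209 with an estimated correlation), ubiquitin and autophagy 7 up (adjusted p = 5.7e-06, adjusted p = 0.00404 with an estimated correlation), and NRF2 targets 10 up with HMOX1 at 0.66 and 1 down (adjusted p = 7.14e-05, adjusted p = 0.0353 with an estimated correlation). Of 27 proteasome subunits 10 rose (adjusted p = 0.000431, adjusted p = 0.344 with an estimated correlation). Of the MAPK output genes 15 fell, or 16 when adjusted over the list alone, and ETV5 rose by 0.21, with a mean of -0.36 (adjusted p = 2.06e-05, adjusted p = 0.123 with an estimated correlation). Of the replication genes 22 fell, with E2F8 down by 0.61 and CCNE1 by 0.49, while CDC6 rose by 0.74 and SLBP by 0.17 (adjusted p = 1.11e-06, adjusted p = 0.236 with an estimated correlation). Adjusted over the list alone, 24 replication genes fell and 3 rose. Of the G2/M genes 22 fell and 3 rose, or 24 and 3 when adjusted over the list alone, with PLK1 down by 0.34 and CENPA up by 0.21 (adjusted p = 0.00272, adjusted p = 0.585 with an estimated correlation). All 16 genes of ribosome biogenesis fell (adjusted p = 1.97e-06, adjusted p = 0.0876 with an estimated correlation). NF-kB targets had 9 members down and 1 up, or 11 and 1 when adjusted over the list alone, with NFKBIA down by 0.63 (adjusted p = 0.0303, adjusted p = 0.354 with an estimated correlation), and p53 targets had 8 down and 1 up, or 9 and 1 over the list alone (adjusted p = 0.0399, adjusted p = 0.354 with an estimated correlation). The client kinases and receptors had 12 members down and none up (adjusted p = 0.0587), and this and the other 13 lists were not called.

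At 6 h 1000 nM called 4737 genes, 1664 up and 3073 down, of which 33 rose and 4 fell at least 2-fold, the 4 being HES1, DLX2, IER3 and CYP1B1. When lines were not paired the count was 263. Centring each array gave 3754 genes up and 1851 down.

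**Figure D2:**
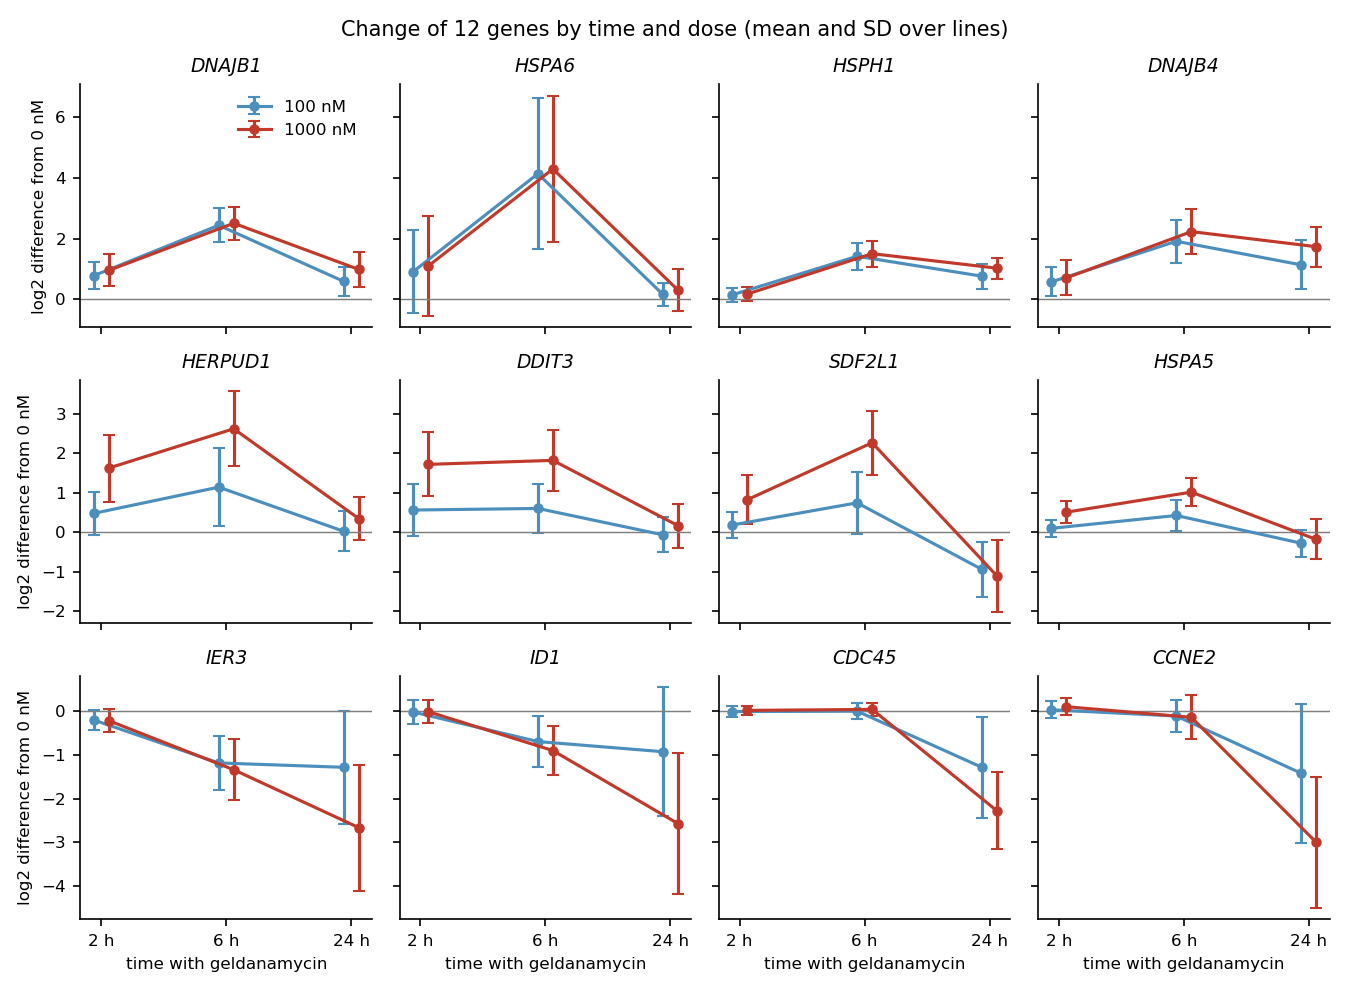
Mean difference from 0 nM (log2) of 12 genes against time in h, for 100 nM (blue) and 1000 nM (red), with bars of SD over lines. At 6 h DNAJB1 had reached 2.44 and 2.50 at the 2 doses, while HERPUD1 had reached 1.14 and 2.62.

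Which genes moved first, within 2 h of 1000 nM? The ER stress genes DDIT3 and HERPUD1 rose by 1.72 ± 0.11 and 1.63 ± 0.11, each in 52 of 52 lines (adjusted p = 1.02e-18 and 5.89e-17). DNAJB9 rose by 1.30 ± 0.10 in 52 lines, the mTOR inhibitor gene DDIT4 by 1.17 ± 0.14 in 49 and the glutathione-degrading enzyme gene CHAC1 by 0.89 ± 0.12 in 46. Of the heat shock genes HSPA6 rose by 1.09 ± 0.22 in 42 lines (adjusted p = 0.000599), DNAJB1 by 0.95 ± 0.07 in 51 (adjusted p = 3.93e-16), DNAJB4 by 0.71 ± 0.08 in 52 and HSPH1 by 0.18 ± 0.03. HSPA5 rose by 0.51 ± 0.04 in 51 lines, SDF2L1 by 0.83 ± 0.08 in 50, ZNF165 by 1.03 ± 0.11 in 48, MIS12 by 0.62 ± 0.06 in 50 and FICD by 0.57 ± 0.08 in 42. Falls were small. HES1 fell by 0.27 ± 0.04 in 42 lines, the cyclin F gene CCNF by 0.25 ± 0.03 in 46, NFKBIA by 0.22 ± 0.03 in 45, the phosphatase gene PPM1D by 0.19 ± 0.03 in 44 and the mitotic kinase gene PLK1 by 0.18 ± 0.03 in 43. HSF1 at -0.06 was not called (adjusted p = 0.367).

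Of the ER unfolded protein response genes 17 rose at 2 h, with a mean of 0.43 (adjusted p = 1.97e-60, adjusted p = 5.26e-06 with an estimated correlation). Of the ATF4 genes 14 rose, or 16 when adjusted over the list alone (adjusted p = 8.17e-34, adjusted p = 0.000469 with an estimated correlation), and of the HSF1 chaperones 12, or 15 (adjusted p = 3.43e-27, adjusted p = 1.32e-05 with an estimated correlation). Of 31 G2/M genes 14 fell and none rose, or 17 fell when adjusted over the list alone (adjusted p = 6.61e-17, adjusted p = 0.00366 with an estimated correlation). The cholesterol synthesis genes HMGCS1 and IDI1 rose by 0.18 and 0.16, and over the list alone 4 rose and 1 fell (adjusted p = 0.000934, adjusted p = 0.00865 with an estimated correlation). HSP90 co-chaperones had 2 members up (adjusted p = 0.00731, adjusted p = 0.0683 with an estimated correlation) and ubiquitin and autophagy 2 up (adjusted p = 0.0318, adjusted p = 0.204 with an estimated correlation). In the MAPK list FOS rose by 0.33 and EGR1 by 0.21 while IER3 fell by 0.21 and SPRY1 by 0.13, and neither it nor the other 19 lists were called (adjusted p = 0.648 for MAPK output).

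At 2 h 368 genes were called, 192 up and 176 down, and the 6 that rose at least 2-fold were DDIT3, HERPUD1, DNAJB9, DDIT4, HSPA6 and ZNF165. Unpaired, 9 genes were called. Centring each array gave 242 up and 113 down.

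What did 100 nM do at 24 h? DHRS2, a dehydrogenase gene, rose by 1.46 ± 0.22 in 49 of 57 lines (adjusted p = 1.46e-07), CLU by 1.37 ± 0.12 in 55 (adjusted p = 7.11e-14), H2AC6 by 1.25 ± 0.16 in 48, DNAJB4 by 1.13 ± 0.10 in 52, CCNG2 by 0.97 ± 0.14 in 48 and the histone gene H2BC21 by 0.95 ± 0.13 in 49. HSPH1 rose by 0.76 ± 0.05 in 57 lines and DNAJB1 by 0.59 ± 0.06 in 51. The ribonucleotide reductase gene RRM2 fell by 1.31 ± 0.14 in 55 lines (adjusted p = 2.74e-11), CDC45 by 1.28 ± 0.15 in 50, PRIM1 by 1.28 ± 0.11 in 56, IER3 by 1.28 ± 0.17 in 49, FOSL1 by 1.24 ± 0.17 in 48, CDC6 by 1.19 ± 0.15 in 52 and HSPA5 by 0.27 ± 0.04. Of the HSF1 chaperones 21 rose (mean 0.52, adjusted p = 7.24e-21, adjusted p = 0.00693 with an estimated correlation). All 28 replication genes fell (mean -0.78, adjusted p = 7.51e-18, adjusted p = 0.155 with an estimated correlation) and 16 MAPK output genes fell (mean -0.60, adjusted p = 1.91e-06, adjusted p = 0.236 with an estimated correlation). Ribosome biogenesis had 13 members down (adjusted p = 1.79e-05, adjusted p = 0.356 with an estimated correlation), ATF4 12 down and 1 up (adjusted p = 0.00274, adjusted p = 0.344 with an estimated correlation) and the proteasome 14 down and 3 up (adjusted p = 0.0125, adjusted p = 0.633 with an estimated correlation). Ubiquitin and autophagy had 7 up (adjusted p = 0.00521, adjusted p = 0.322 with an estimated correlation), and cytosolic ribosomal proteins 14 up and 1 down, or 15 and 3 when adjusted over the list alone (adjusted p = 0.00848, adjusted p = 0.541 with an estimated correlation). The ER list had 9 members down and 2 up and was not called (adjusted p = 0.0587). In all, 100 nM called 5311 genes at 24 h, 2540 up and 2771 down, and 900 without pairing. Centring gave 3302 up and 2324 down. At least 2-fold, 23 genes fell and 4 rose, DHRS2, CLU, H2AC6 and DNAJB4.

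At 6 h 100 nM raised HSPA6 by 4.13 ± 0.32 in 54 of 56 lines (adjusted p = 9.61e-17), DNAJB1 by 2.44 ± 0.07 in 56 (adjusted p = 4.11e-37), BAG3 by 2.13 ± 0.09 in 56, DNAJB4 by 1.91 ± 0.09 in 56, HSPH1 by 1.42 ± 0.06 in 56 and HSPA4L by 1.28 ± 0.08 in 55. The ER genes moved less, HERPUD1 rising by 1.14 ± 0.13 in 51 lines and HSPA5 by 0.43 ± 0.05 in 51. IER3 fell by 1.18 ± 0.08 in 53 lines, DLX2 by 1.03 ± 0.11 in 51, CYP1B1 by 1.01 ± 0.11 in 49, HES1 by 0.82 ± 0.07 in 53, TIPARP by 0.77 ± 0.08 in 53 and IER2 by 0.74 ± 0.05 in 56. All 22 HSF1 chaperones rose (adjusted p = 1.79e-58, adjusted p = 5.25e-06 with an estimated correlation), 7 HSP90 co-chaperones rose and 2 fell (adjusted p = 7.41e-08, adjusted p = 0.00108 with an estimated correlation), and 19 of 20 ER genes rose (mean 0.39, adjusted p = 1.43e-15, adjusted p = 0.0978 with an estimated correlation). ATF4 had 16 members up (adjusted p = 4.72e-10, adjusted p = 0.154 with an estimated correlation), the proteasome 14 up (adjusted p = 1.26e-05, adjusted p = 0.158 with an estimated correlation), ubiquitin and autophagy 6 up (adjusted p = 0.000228, adjusted p = 0.0464 with an estimated correlation) and NRF2 targets 8 up and 1 down, or 8 and 2 when adjusted over the list alone (adjusted p = 0.000458, adjusted p = 0.0649 with an estimated correlation). Interferon-stimulated genes had 7 up and 1 down, or 7 and 2 over the list alone (adjusted p = 0.0475, adjusted p = 0.466 with an estimated correlation).

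MAPK output had 14 members down and 1 up at this dose and time, or 15 and 1 when adjusted over the list alone, and this call held (adjusted p = 4.77e-08, adjusted p = 0.0291 with an estimated correlation). G2/M had 19 down and 3 up, or 24 and 3 over the list alone (adjusted p = 1.11e-06, adjusted p = 0.344 with an estimated correlation), and replication 14 down and 1 up, or 15 and 2 (adjusted p = 7.14e-05, adjusted p = 0.344 with an estimated correlation). Ribosome biogenesis had 14 down, or 15 over the list alone (adjusted p = 1.25e-06, adjusted p = 0.062 with an estimated correlation), p53 targets 7 down and 1 up (adjusted p = 0.0399, adjusted p = 0.354 with an estimated correlation), and NF-kB targets 6 down and 1 up, or 8 and 1 (adjusted p = 0.0154, adjusted p = 0.354 with an estimated correlation). In all, 3261 genes were called, 1304 up and 1957 down, 66 without pairing, and 2213 up and 1287 down with each array centred. At least 2-fold, 10 rose and 3 fell, CYP1B1, DLX2 and IER3.

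At 2 h 100 nM raised HSPA6 by 0.91 ± 0.18 in 43 of 52 lines (adjusted p = 0.00148), DNAJB1 by 0.78 ± 0.06 in 52 (adjusted p = 1.11e-14), DDIT4 by 0.73 ± 0.12 in 48, DNAJB4 by 0.58 ± 0.06 in 51, HERPUD1 by 0.48 ± 0.07 in 50 and RGS2 by 0.42 ± 0.05 in 47. HES1 fell by 0.26 ± 0.04 in 44 lines, CCNF by 0.23 ± 0.03 in 43, IER3 by 0.20 ± 0.03 in 44, PPM1D by 0.19 ± 0.03 in 46, the centromere chaperone gene HJURP by 0.18 ± 0.02 in 48 and PLK1 by 0.17 ± 0.02 in 47. Of the HSF1 chaperones 8 rose, or 14 when adjusted over the list alone (adjusted p = 2.82e-32, adjusted p = 5.25e-06 with an estimated correlation). ATF4 had 6 members up, or 10 (adjusted p = 1.15e-17, adjusted p = 0.00923 with an estimated correlation), the ER list 4 up, or 7 (adjusted p = 9.53e-12, adjusted p = 0.0101 with an estimated correlation), and HSP90 co-chaperones 1 up, or 3 (adjusted p = 0.000756, adjusted p = 0.0179 with an estimated correlation). The 1 co-chaperone gene up, CHORDC1, is also in the list of HSF1 chaperones. G2/M had 6 down, or 22 over the list alone (adjusted p = 4.39e-27, adjusted p = 0.000267 with an estimated correlation). MAPK output had 1 up and 1 down, or 2 and 4 (adjusted p = 0.0479, adjusted p = 0.361 with an estimated correlation). The client kinases had 1 down, PLK1, which is also in the G2/M list (adjusted p = 0.0345, adjusted p = 0.0716 with an estimated correlation). The epithelial markers had 0 either way (adjusted p = 0.0321, adjusted p = 0.403 with an estimated correlation). Their score was above 0 in only 24 of 52 lines, with a mean of 0.03, an SD of 0.17 and a highest line at 1.03. Here 100 genes were called, 42 up and 58 down, 1 without pairing, and 46 up and 36 down with each array centred. By limma's test 0 genes were called and changed at least 2-fold, as by the signed-rank test, and 1137 genes had an unadjusted p below 0.05.

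Did the higher dose do more than the lower? The 1000 nM arrays were set directly against the 100 nM arrays of the same lines. At 6 h some heat shock genes were not called different, DNAJB1 at 0.07 (95% interval 0.01 to 0.13, higher in 31 of 55 lines, adjusted p = 0.137) and HSPA6 at 0.11 (-0.09 to 0.32, adjusted p = 0.544). Others stood slightly higher at 1000 nM, DNAJB4 by 0.29 (0.22 to 0.36) in 49 lines (adjusted p = 1.48e-09), BAG3 by 0.19 (0.13 to 0.26) in 46 (adjusted p = 1.91e-06) and HSPH1 by 0.07 (0.02 to 0.12) in 37 (adjusted p = 0.029). The ER genes stood further apart, SDF2L1 by 1.52 ± 0.11 (1.29 to 1.74) in 55 of 55 lines (adjusted p = 9.39e-17), HERPUD1 by 1.49 ± 0.12 (1.25 to 1.74) in 55, DNAJB9 by 1.45 ± 0.13 (1.20 to 1.70) in 52, DDIT3 by 1.22 ± 0.10 (1.02 to 1.42) in 52 and HSPA5 by 0.58 (0.49 to 0.68) in 53. SEL1L stood 1.05 ± 0.07 and FICD 1.05 ± 0.10 higher. All 20 ER genes were called higher, with a mean of 0.81 (adjusted p = 2.11e-73, adjusted p = 3.12e-05 with an estimated correlation). Of the HSF1 chaperones 8 were called higher, with a mean of 0.07 (adjusted p = 2.08e-07, adjusted p = 0.164 with an estimated correlation). PCGF3 stood 0.51 ± 0.05 lower in 54 lines, CYP1B1 0.37 ± 0.06 lower in 45, TGOLN2 0.28 ± 0.03 lower in 52 and CD59 0.26 ± 0.03 lower in 52. Of the ATF4 genes 15 were higher, or 18 when adjusted over the list alone (adjusted p = 5.12e-20, adjusted p = 0.0135 with an estimated correlation). Of the replication genes 14 were lower and 1 higher, or 16 and 2 over the list alone (adjusted p = 2.89e-06, adjusted p = 0.0509 with an estimated correlation). At 6 h 1666 genes differed, 597 higher and 1069 lower, against 41 without pairing and against 870 higher and 536 lower with each array centred.

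By 24 h other genes separated the doses. RGS2 stood 0.83 ± 0.11 higher at 1000 nM in 48 of 57 lines (adjusted p = 9.29e-09), CCNG2 0.76 ± 0.09 in 51, the ER genes CRELD2 0.68 ± 0.10 in 48 and PDIA4 0.62 ± 0.06 in 54, RSRP1 0.66 ± 0.07 in 53 and the CDK inhibitor gene CDKN1C 0.63 ± 0.11 in 46. ID1 stood 1.65 ± 0.18 lower in 53 lines (adjusted p = 4.54e-11), CCNE2 1.58 ± 0.17 lower in 49, DUSP6 1.51 ± 0.16 lower in 53, ID3 1.39 ± 0.17 lower in 48, MAFF 1.39 ± 0.16 lower in 50 and IER3 1.38 ± 0.14 lower in 53. DNAJB1 was 0.39 higher (0.30 to 0.49), and HSPA5 at 0.10 was not called (adjusted p = 0.176). All 28 replication genes were lower (adjusted p = 4.05e-17, adjusted p = 0.154 with an estimated correlation), as were 19 of 20 MAPK output genes with a mean of -0.73 (adjusted p = 7.83e-12, adjusted p = 0.0444 with an estimated correlation). Of the ER genes 17 were higher and 1 lower (adjusted p = 2.09e-09, adjusted p = 0.0389 with an estimated correlation), and of the HSF1 chaperones 20 were higher, or 21 over the list alone (adjusted p = 8.65e-12, adjusted p = 0.115 with an estimated correlation). The doses differed in 5045 genes at 24 h, 2392 higher and 2653 lower, and in 137 without pairing. With each array centred the count was 8315, with 6660 higher and 1655 lower, so the split between higher and lower at this step rests on the scaling.

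At 2 h DDIT3 stood 1.15 ± 0.07 higher at 1000 nM in 52 of 52 lines (adjusted p = 5.44e-20), HERPUD1 1.14 ± 0.08 in 52, DNAJB9 0.95 ± 0.07 in 50, ZNF165 0.84 ± 0.09 in 47, SDF2L1 0.64 ± 0.06 in 48 and FICD 0.50 ± 0.05 in 48. TMEM165, a Golgi transporter gene, stood 0.23 ± 0.04 lower in 42 lines. Of the ER genes 15 were higher, or 18 over the list alone (adjusted p = 6.62e-79, adjusted p = 1.52e-07 with an estimated correlation), and of the HSF1 chaperones 2, or 4 (adjusted p = 0.0053, adjusted p = 0.236 with an estimated correlation). The count at 2 h was 87 genes, 73 higher and 14 lower, and 4 without pairing.

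**Figure D3:**
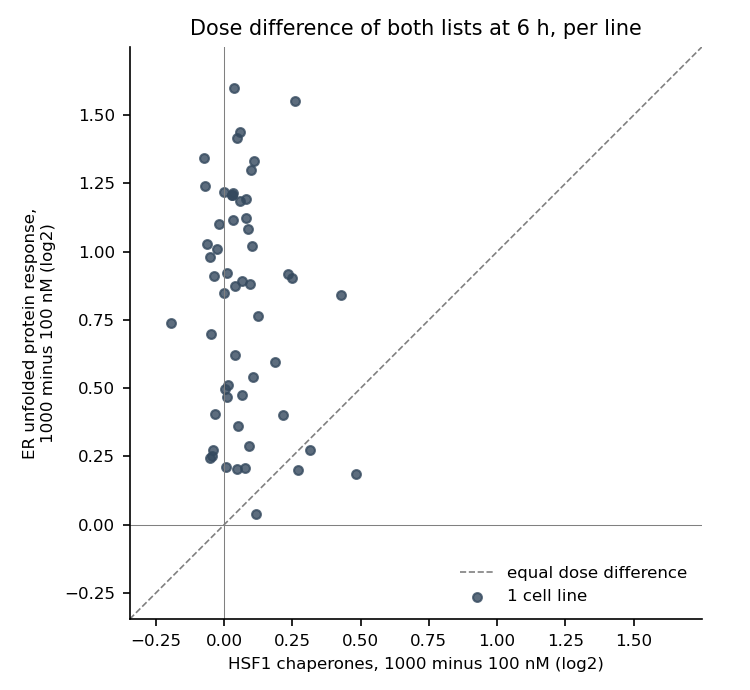
Mean 1000 minus 100 nM difference (log2) at 6 h of the HSF1 chaperones on the x axis and of the ER unfolded protein response genes on the y axis, 1 point per line, for 55 lines. The dashed line marks equal differences, and 51 of 55 lines lie above it.

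How did the 1000 nM effect shift between time points? From 6 to 24 h the effect on HSPA6 dropped by 3.97 ± 0.29 in 55 of 56 lines (adjusted p = 5.97e-18), on SDF2L1 by 3.39 ± 0.16 in 56, on CCNE2 by 2.88 ± 0.19 in 55, on CDC6 by 2.75 ± 0.17 in 55, on MANF by 2.49 ± 0.11 in 56 and on CDC45 by 2.35 ± 0.12 in 56. The effect on H2AC6 grew by 1.49 ± 0.18 in 47 lines, on TTC17 by 1.46 ± 0.07 in 56, on DHRS2 by 1.44 ± 0.23 in 47, on RSRP1 by 1.39 ± 0.06 in 56, on CLU by 1.37 ± 0.10 in 54 and on TMT1A by 1.32 ± 0.17 in 51. Of the ER genes 19 had a lower effect at 24 h, or 20 over the list alone (adjusted p = 2.48e-14, adjusted p = 0.029 with an estimated correlation), and all 28 replication genes did (adjusted p = 3.44e-23, adjusted p = 0.05 with an estimated correlation). The HSF1 chaperones were split, 8 lower and 5 higher, or 8 and 6 over the list alone (adjusted p = 0.277). From 2 to 6 h the effect on HSPA6 grew by 3.05 ± 0.29 in 47 of 51 lines (adjusted p = 5.06e-13), on BAG3 by 1.85 ± 0.08 in 51, on DNAJB1 by 1.47 ± 0.09 in 49, on SDF2L1 by 1.46 ± 0.10 in 48, on DNAJB4 by 1.44 ± 0.10 in 50 and on HSPA4L by 1.37 ± 0.07 in 51. The effect on IER3 dropped by 1.25 ± 0.07 in 51 lines, on CYP1B1 by 1.20 ± 0.13 in 45, on DLX2 by 1.15 ± 0.13 in 46 and on ID1 by 0.92 ± 0.08 in 48. All 22 HSF1 chaperones had a higher effect at 6 than at 2 h (adjusted p = 1.65e-52, adjusted p = 1.51e-06 with an estimated correlation), as did 19 ER genes (adjusted p = 1.48e-39, adjusted p = 0.00058 with an estimated correlation). The effect differed between 24 and 6 h for 5779 genes, 2942 higher and 2837 lower at 24 h, and between 6 and 2 h for 3033, 1078 higher and 1955 lower at 6 h. With each array centred 66.6% of the former and 61.3% of the latter were higher, against 50.9% and 35.5% without centring.

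What changed over time without drug? From 2 to 24 h at 0 nM DDIT4 rose by 1.38 ± 0.15 in 48 of 52 lines (adjusted p = 4.79e-11), ZNF322 by 1.01 ± 0.05 in 51, IDH1 by 0.66 ± 0.06 in 51, TUBD1 by 0.64 ± 0.05 in 49 and TOB2 by 0.63 ± 0.05 in 50. The stress gene ATF3 fell by 1.35 ± 0.11 in 49 lines, the YAP targets CCN2 and CCN1 by 1.27 ± 0.09 in 52 and 1.14 ± 0.12 in 51, the chemokine gene CXCL8 by 1.11 ± 0.16 in 45 and MAFF by 1.09 ± 0.13 in 46. All 13 cholesterol synthesis genes rose (adjusted p = 1.76e-07, adjusted p = 0.15 with an estimated correlation), and 10 genes of TGF-beta and extracellular matrix fell (adjusted p = 4.57e-06, adjusted p = 0.0409 with an estimated correlation). From 6 to 24 h DDIT4 rose by 0.76 ± 0.12, MBD5 by 0.71 ± 0.06, the sterol regulator gene INSIG1 by 0.70 ± 0.10, PNRC1 by 0.69 ± 0.08 and H2AC6 by 0.69 ± 0.09, and SPHK1 fell by 0.74 ± 0.09, CXCL8 by 0.74 ± 0.14, PMEPA1 by 0.73 ± 0.09, TAGLN by 0.67 ± 0.08 and FOSL1 by 0.67 ± 0.08. Between 2 and 24 h 3942 genes were called, 2255 up and 1687 down, and 50 without pairing. Between 6 and 24 h the count was 4696, 2463 up and 2233 down, and 140 without pairing. With each array centred the splits reversed to 1685 up and 2591 down, and to 1876 up and 3249 down.

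Did the tissue of origin shape the 1000 nM effect? Values here are mean effects per tissue, and the test is of their difference from the other tissues. The 0 nM levels of the genes named by tissue, at 24 h or 6 h, were not compared between tissues. A gene near background in some tissues could not be seen to fall there, so a difference in effect may reflect a difference in level. At 24 h the effect on the leukocyte genes IL10RA and RGS1 was highest in leukemia, at 2.83 and 2.74, and lowest at -0.06 in prostate and -0.08 in colon lines (adjusted p of the F test 3.31e-10 and 5.21e-10). ENPP2, the autotaxin gene, stood at 3.75 in the 4 leukemia lines against a mean of 0.42 in the other tissues (adjusted p = 1.01e-07), RGS2 at 4.47 against 1.40 (adjusted p = 0.00469) and PHLDA1 at 1.73 against -1.17. CAD, the gene that starts pyrimidine synthesis, stood at -2.97 in leukemia against -0.86 elsewhere, and DNPH1 at -2.78 against -0.39. These leukemia values count the nearly alike K-562 and HL-60 as 2 lines. In melanoma the ERK feedback genes SPRY2 and SPRY4 stood at -3.81 and -3.99 against -1.18 and -1.40 elsewhere, each below 0 in 9 of 9 lines (adjusted p = 1.36e-06 and 2.89e-05). ST8SIA1, the GD3 synthase gene, stood at -2.67 in melanoma against 0.01 elsewhere (adjusted p = 2.91e-13) and MANSC1 at -2.16 against 0.36, while KCNJ13 stood at 2.56 against 0.17 (adjusted p = 1.84e-10), HAS2 at 2.08 against -0.48 and TGFB2 at 2.03 against -0.18. In colon lines SELENOP stood at 3.39 against 0.92 (adjusted p = 0.00261), SPINK1 at 2.63 against 0.19 (adjusted p = 4.73e-05) and PMM1 at 1.90 against 0.15. In renal lines CDKN1C stood at 3.03 against 0.89 (adjusted p = 0.00289), FGFR2 at 2.48 against 0.39 and DEFB1 at 2.43 against 0.24, and INHBA stood at -1.80 against -0.10. In CNS lines DTNA stood at 1.26 against -0.11 (adjusted p = 0.0274) and NRG1 stood at -1.54 against -0.22 (adjusted p = 0.00922). In lung lines the 3 genes that differed were RARB by 1.29 ± 0.19, LGSN by 0.98 ± 0.19 and ATP1B3 by 0.70 ± 0.14. With 1 label kept per shared source, up to 7 of 100 random tissue labels gave as many genes for CNS and for lung lines at 24 h, so chance was not excluded for these 2 counts.

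At 6 h HSPA6 stood at 1.27 in melanoma against 4.85 in the other tissues, with a difference of -3.58 ± 0.74 and 8 of 9 melanoma lines above 0 (adjusted p = 0.0141). The T-box gene TBX2 stood at -1.01 in melanoma against -0.07 elsewhere (adjusted p = 4.42e-06), DACT1 at -1.15 against -0.24 and the lineage factor SOX10 at -0.61 against 0.03. In leukemia BAG3 stood at 3.62 against 2.19 (adjusted p = 0.00264), MBNL2 at 2.38 against 0.83 and SERPINH1 at 2.50 against 1.10, but these calls count the nearly alike K-562 and HL-60 as 2 lines. In colon lines EREG, an EGFR ligand gene, stood at -1.48 against -0.27 (adjusted p = 0.00843). In CNS lines 5 genes differed, GDF15 by 1.23 ± 0.26, KRT8 by 0.39 ± 0.07, RRP9 by 0.36 ± 0.07, NDP by -0.70 ± 0.11 and GASK1B by -0.68 ± 0.14, and in renal lines 3, MAP3K7CL by 0.69 ± 0.12, KDM7A by 0.61 ± 0.12 and TLE3 by 0.53 ± 0.10. With 1 label kept per shared source, up to 11 of 100 random tissue labels gave as many genes for leukemia and for CNS lines at 6 h, so chance was not excluded for these 2 counts. For colon and renal lines up to 3 of 100 did, with the highest above the real count, so chance was not excluded there either.

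The F test called 3116 genes at 24 h and 71 at 6 h, against 647 and 0 with the Kruskal-Wallis test. At 2 h limma called 0 genes over 8 tissues and 52 lines, 524 had an unadjusted p below 0.05, and the Kruskal-Wallis test called 0. Set against the other tissues at 24 h, leukemia differed in 2080 genes, melanoma in 1690, colon in 591, renal in 202, CNS in 23 and lung in 3. Breast and ovarian lines differed in 0 genes by limma's test, with 1018 and 969 at an unadjusted p below 0.05. At 6 h leukemia differed in 113 genes, melanoma in 29, colon in 28, CNS in 5, renal in 3, and breast, lung and ovarian lines in 0, with 593, 950 and 529 at an unadjusted p below 0.05. Leaving out K-562 or HL-60, whose arrays are nearly alike, left 1074 or 1050 leukemia genes at 24 h and 45 or 28 at 6 h.

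The lists of lineage and signalling genes were also read within tissues. In the 9 melanoma lines the melanocyte markers rose at 24 h by 0.44 ± 0.31 (SD) at 100 nM and 0.47 ± 0.31 (SD) at 1000 nM, each in 8 of 9 lines (exact sign-flip permutation p = 0.00781, adjusted p = 0.0234, smallest possible p 0.00391). At 6 h they fell at 1000 nM by 0.08 ± 0.09 (SD) in 7 of 9 lines (exact permutation p = 0.0234, adjusted p = 0.0469). The 9 labels include LOX, nearly alike to the colon line HCT-116, and M14 and MDA-MB-435, which share a source. The exact test took all of them as independent, so its p-values may be too small. Without LOX the markers rose at 24 h by 0.51 at 100 nM and 0.55 at 1000 nM, each in all 8 other lines. The MAPK output score at 24 h was -2.03 ± 0.40 (SD) in 9 melanoma lines and -1.20 ± 0.65 (SD) in 48 others (permutation p = 0.00035). This test too took all labels as independent. Without LOX the difference was -0.92 (permutation p = 0.00017). At 6 h the difference between the 9 melanoma lines and the others was -0.00 (permutation p = 0.964).

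**Figure D4:**
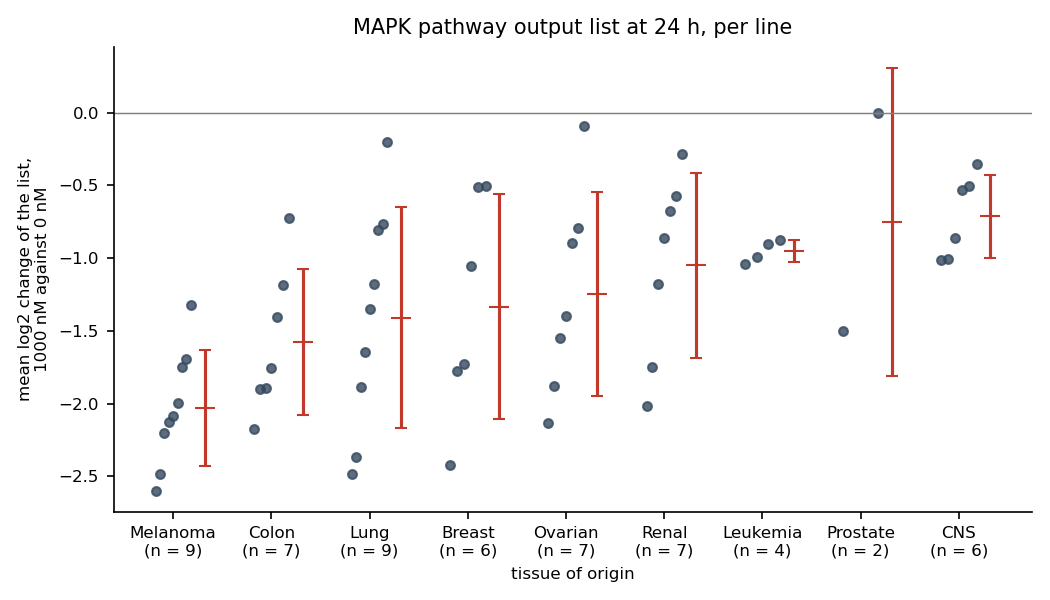
MAPK output score (1000 minus 0 nM at 24 h, log2) by tissue of origin, 1 point per line with the mean and SD per tissue. Melanoma lines had the lowest mean, -2.03, and CNS lines the highest, -0.71.

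Did the level of a gene before treatment go with the heat shock response? The heat shock score was the mean over the HSF1 chaperones, and the levels of HSF1, HSP90AA1, HSP90AB1, NQO1 and ABCB1 were taken from 0 nM arrays of other time points, which gave 30 correlations. The level of HSF1 went with the score at 2 h, with a Pearson r of 0.51 at 1000 nM (permutation p = 0.00017, adjusted p = 0.0051) and 0.46 at 100 nM (permutation p = 0.00089, adjusted p = 0.0133). Spearman's rho for these was 0.41 (p = 0.0029, adjusted p = 0.0422) and 0.36 (p = 0.00845, adjusted p = 0.0422). Within tissues r was positive in 6 of 7 tissues at both doses, from -0.03 to 0.91 at 1000 nM and from -0.66 to 0.76 at 100 nM. Without the 2 lines farthest from the median HSF1 level r was 0.52 and 0.45. At 1000 nM and 6 h r was 0.37 (p = 0.00485, adjusted p = 0.0485), positive in 4 of 6 tissues and 0.35 without the 2 farthest lines, and 0.36 without NCI-H460, K-562, TK-10 and LOX, a choice made after the data were seen that ended the call (adjusted p = 0.0774). At 100 nM and 6 h r was 0.33 and not called (adjusted p = 0.0615), with a rho of 0.36 (adjusted p = 0.0422). With a score of DNAJB1 and HSPH1 alone, for which no test was run, r was lower. It was 0.39 at 1000 nM and 0.31 at 100 nM at 2 h, and 0.21 and 0.15 at 6 h. At 24 h r was 0.05 at 100 nM and 0.13 at 1000 nM, positive in 3 and 2 of 7 tissues, and neither was called (adjusted p = 0.772 and 0.502). The level of HSP90AA1 had a rho of -0.37 with the score at 100 nM and 24 h (p = 0.00533, adjusted p = 0.0422), but its r of -0.32 was not called (adjusted p = 0.0615), with r at -0.44 without the 2 farthest lines and positive in 2 of 7 tissues. At its other doses and times, and for HSP90AB1 at all 6, neither r nor rho was called. NQO1, whose enzyme reduces geldanamycin, had r from -0.24 to -0.02 and was not called. Within tissues its r at 24 h was positive in 0 of 7 tissues at 1000 nM (-0.66 to -0.09) and in 1 of 7 at 100 nM. At 2 h it was positive in 2 of 7 at both doses, and at 6 h in 3 of 7 at 100 nM and 3 of 6 at 1000 nM. These signs were not tested. ABCB1 lay above 9.08 in 4 lines and at or below 6.11 in the rest. In the 52 lines of lower ABCB1 r with the 1000 nM score at 6 h was -0.34 (adjusted p = 0.0615), with a rho of -0.36 (adjusted p = 0.0422). With the 4 high lines included, r was -0.12. At 24 h r in the lower lines was -0.18 at 100 nM and -0.16 at 1000 nM, and neither was called (adjusted p = 0.395 and 0.411). With the 4 high lines included it was -0.34 and -0.33, for which no test was run. Most of the lower lines had ABCB1 below every array median, where the order is largely one of signal near background.

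The RNA of treated arrays was checked through the 3 prime and 5 prime control probe sets. GAPDH had a 3 prime minus 5 prime signal 0.03 higher at 1000 nM and 24 h, in 41 of 57 lines (permutation p = 0.00146, adjusted p = 0.0175), and ACTB 0.06 higher in 40 (adjusted p = 0.071). No other dose or time point had an adjusted p below 0.05.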

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

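Chosen after the result was seen were the tests of single swapped arrays, of 1 line under both labels, of shared tissue and of pairs with different tissues, the splits with 1 label per shared source, the test of the normalization, the 2 h test of the doses the lists need, the test of raised heat shock genes in a 0 nM array, and the bound from other lines in the test of a swap.

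In 3 of 40 groups of lines 1 line lay far from the others of its tissue in the mean change of the HSF1 chaperones at 1000 nM, where chance alone marks about 1 in 20 groups. At 6 h NCI-H460 was at -0.0052, while the other lung lines were at 0.87 to 1.42 (n = 9). At 24 h COLO-205 was at 0.28, while the other colon lines were at 0.67 to 0.92 (n = 7), and NCI-ADR-RES was at 0.23, while the other ovarian lines were at 0.71 to 0.89 (n = 7).

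The 1000 nM effect differed between 24 and 6 h for 5779 genes and between 6 and 2 h for 3033. It differed between tissues for 3116 genes at 24 h and 71 at 6 h. Single tissues differed from the others at 24 h for 23 genes in CNS, 591 in colon, 2080 in leukemia, 3 in lung, 1690 in melanoma and 202 in renal lines, and at 6 h for 5 in CNS, 28 in colon, 113 in leukemia, 29 in melanoma and 3 in renal lines. The MAPK output score differed between melanoma and other lines by -0.83 at 24 h.

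Each count was set against 100 splits of the same arrays, the real one included, with doses, time points or tissue labels swapped at random. Chance can be excluded for the counts of genes called by dose and time, each reached by 1 of the 100 splits. The highest other splits gave 4, 1 and 5 genes for 1000 nM at 24, 6 and 2 h (real 6796, 4737 and 368) and 1, 2 and 3 for 100 nM (real 5311, 3261 and 100). They gave 42, 1 and 5 for 1000 against 100 nM (real 5045, 1666 and 87), 1 and 2 for the effects over time, and 10 and 2 for 0 nM over time (real 3942 and 4696). For genes changed at least 2-fold every other split gave 0. The real split gave 0 too for 100 nM at 2 h, a count that any split reaches, so it was not tested. Chance can also be excluded for the tissue test at 24 h (real 3116, highest other 913). At 6 h (real 71, highest other 76, 2 of 100 splits as large) it is made unlikely but not excluded. For single tissues it can be excluded at 24 h for leukemia (2080, highest other 96), melanoma (1690, 18), colon (591, 29) and renal lines (202, 33), and at 6 h for melanoma (29, 2). For colon (28, 2) and renal lines (3, 2) at 6 h no other split of all lines gave as many. These splits take labels of 1 source as independent lines, so the tissue splits were drawn again with 1 label per shared source, once without K-562, TK-10, LOX, NCI-ADR-RES, SNB-19 and MDA-MB-435 and once without HL-60, OVCAR-8, HCT-116, NCI-ADR-RES, U251 and M14. In both sets each of the results just named kept a share below 5 of 100 splits, though the highest other split passed the real count for the tissue test at 6 h (21 and 5 genes, highest others 53 and 50, 3 and 4 of 100 splits), for colon lines at 6 h (18 and 25, highest others 23 and 35, 2 of 100 splits in each) and for renal lines at 6 h in the second (4, highest other 10, 3 of 100 splits). Chance is therefore not excluded for these counts at 6 h. For leukemia at 24 h the counts were 1008 and 957, and the highest others 237 and 519. Chance cannot be excluded for leukemia at 6 h, where all lines gave 113 genes (highest other 163, 2 of 100 splits) but the 2 sets gave 34 and 23 (highest others 278 and 221, 11 and 9 of 100 splits). It cannot be for CNS lines, which had 23 genes at 24 h (highest other 19) but 12 and 5 in the 2 sets (25 and 52, 5 and 7 of 100 splits), and 5 at 6 h (highest other 8, 3 of 100 splits) but 5 and 2 in the 2 sets (6 and 36, 2 and 11 of 100 splits). Nor can it be for lung lines at 24 h, with 3 genes (highest other 37, 2 of 100 splits) but 2 and 1 in the 2 sets (21 and 5, 6 and 7 of 100 splits). Any split reaches a count of 0, so the splits cannot test such counts and chance cannot be judged for them. These were the counts in breast and ovarian lines at 24 h, in breast, lung and ovarian lines at 6 h and over tissues at 2 h. The highest splits gave 192, 69, 18, 2, 3 and 20 genes in that order. The 5 counts of single tissues among these were 0 in both sets too. For lung and breast lines at 24 h the highest splits called 37 and 192 genes, more than the real 3 and 0, while the median split called 0, as it did in the 2 sets for leukemia at 6 h, where the highest called 278 and 221. Such splits may reflect a structure of the lines other than tissue, and which lines made them up was not tested.

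The 0 nM profiles of K-562 and HL-60 correlated at 0.998, of TK-10 and OVCAR-8 at 0.997 and of LOX and HCT-116 at 0.995, while the next pairs, NCI-ADR-RES with OVCAR-8 and with TK-10, were at 0.987 and 0.985 and the median of 1596 pairs at 0.894. Single arrays swapped between labels are argued against, since 91.7% of the arrays of these lines lay as close to the partner label as arrays of 1 line lie to each other. Shared tissue alone is argued against, since 2 of the 3 pairs carry different tissues and, on the scale of Fisher's z, K-562 and HL-60 lay 10.3 SD and the lowest of the 3 pairs 7.54 SD above the mean of other pairs of 1 tissue, of which the highest lay 4.88 SD above it. A candidate explanation is that 1 line was grown or hybridised under both labels, since the median correlation between single arrays of the 2 labels at different doses or times was 0.980 in the lowest pair, above the 5th percentile of 0.967 for single arrays of 1 line. As NCI-ADR-RES shares its source with OVCAR-8, its 0.985 with TK-10 goes against the TK-10 label, while which label would be wrong in the other 2 pairs, and a close kinship of their lines, stay open.

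At 6 h the heat shock list stood about equal at both doses while the ER list stood higher at 1000 nM, with a gap of 0.74 ± 0.45 (SD) in 51 of 55 lines (permutation p = 1e-05, the smallest the draws can give). A ceiling of the signal is argued against, since 15 risen heat shock genes far below the highest signal, at a median level of 10.2 against 10.9 for the ER genes, differed between doses by a median of 0.067 against 0.86. The normalization of the arrays is argued against, since a scaling moves genes of 1 signal level alike, while 16 ER genes set against heat shock genes within 0.25 of their level kept 86.9% of the gap (standard error 7.81), above 0 in 51 of 55 lines. A lower dose need of the heat shock response may explain the gap. At 2 h the ER list stood further apart in 94.2% of lines, which repeats the pattern in other arrays but does not measure the dose each list needs. At 24 h both lists differed by dose, with heat shock scores of 0.52 at 100 nM and 0.76 at 1000 nM and ER scores of -0.13 and 0.12. Whether other targets of the drug set the ER response was not tested.

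NCI-H460 showed a heat shock score of -0.0052 at 6 h, while the other 55 lines had 1.09 ± 0.27 (SD) and a lowest of 0.55. Degraded RNA is argued against, since the ACTB 3 prime minus 5 prime signal of the array was 0.79 and the 95th percentile of all arrays was 1.37. In its 0 nM array at 6 h HSPA6 stood at 7.50, against 3.99 and 3.51 at 2 and 24 h, but raised heat shock genes there are argued against as the whole cause, since against the 0 nM arrays of 2 and 24 h the score was 0.32, below the lowest of 0.46 of 50 other lines measured in this way. A swap of the 0 nM and a treated array at 6 h is argued against as the whole cause, since both treated arrays were raised too. In them HSPA6 was at 6.79 and 6.63 and DNAJB1 at 10.93 and 11.10 (8.82 and 9.21 in the 0 nM arrays at 2 and 24 h). The lower of the 2 had a list level 0.30 above the higher of its other 0 nM arrays. By the same measure the 0 nM arrays at 6 h of 51 other lines reached at most -0.06, and that of NCI-H460 itself 0.32. HERPUD1 goes the way of a swap with the 100 nM array, at 10.77 in the 0 nM and 9.84 in the 100 nM array at 6 h. It was at 9.72 and 9.60 in the 0 nM arrays at 2 and 24 h. A swap with the 100 nM array therefore stays open as part of the cause. The score of 0.32 also goes against a stressed or outside 0 nM array as the whole cause, so these stay open only as part of it, while a weak response of the line, a biological explanation, stays open, though against the same 0 nM arrays DNAJB1 rose by 2.08 and HSPA6 by 2.88, where the other lines had 2.36 ± 0.43 and 4.24 ± 2.36 (SD).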

How the results depend on the processing

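Chosen after the data were seen were the alternatives without the lines of alike labels, without NCI-H460, without OVCAR-5 and UO-31, without each leukemia line, and the camera test beyond the comparisons with 0 nM. For the counts by dose and time, the tissue test over all tissues and the 2 lists in melanoma, 449 alternatives left the result on its side of the threshold or within 1.5 times its count and 27 did not, and for the counts of single tissues 24 did and 16 did not. Which side held more genes was less stable, as centring each array moved the larger share from down to up for 1000 nM at 6 h, 100 nM at 24, 6 and 2 h, 1000 against 100 nM at 24 and 6 h and the effect at 6 against 2 h, and from up to down for 0 nM over time. Of 58 list calls 37 were lost with an estimated correlation and 1 with fry. The count at 1000 nM and 24 h was 4611 to 9347 over all alternatives but that without pairing. Without pairing by line, the groups being compared as independent arrays, the counts were 2932, 263 and 9 for 1000 nM at 24, 6 and 2 h, 900, 66 and 1 for 100 nM, 137, 41 and 4 for 1000 against 100 nM, 50 for 24 against 2 h and 140 for 24 against 6 h at 0 nM, where the large differences between lines enter the error. With an adjusted p below 0.01, a stricter threshold, they were 216 for 1000 nM and 59 for 100 nM at 2 h, 1039 for 1000 against 100 nM at 6 h, and 1629 and 10 for the tissue test at 24 and 6 h. Leaving out lines gave 65 without melanoma and 63 without colon lines for 100 nM at 2 h, 14 without melanoma for genes changed at least 2-fold by 100 nM at 24 h, and 1 without melanoma for those at 2 h. For the tissue test at 6 h it gave 46 without 3 derivative lines, 46 without K-562, TK-10 and LOX, and 25 without these and their 3 partners. Array weights gave 6 genes changed at least 2-fold by 100 nM at 24 h, centring each array gave 8315 genes for 1000 against 100 nM at 24 h, and the Kruskal-Wallis test gave 647 and 0 genes for tissues at 24 and 6 h, and for these the cause was not tested. Leukemia differed in 1050 genes at 24 h without HL-60, 1074 without K-562, 2127 without RPMI-8226, 2217 without SR, 1111 without K-562, TK-10 and LOX and 347 without all 6 lines of alike labels. At 6 h these counts were 28, 45, 111, 153, 46 and 16. Without K-562, TK-10 and LOX breast lines had 5 genes at 24 h, and CNS lines 3 and lung lines 1 at 6 h. Without all 6, breast, CNS and lung lines had 1, 13 and 1 at 24 h, and CNS and renal lines 3 and 10 at 6 h. No version without pairing was run for the time differences of effects or the tissue test. Of the genes named, RPS15, RPL35 and RPL7 at 6 h, PSMA4, TRPM1 and RAB27A changed sign under 1 alternative each and were then not called. Signal near the background limits the falls that can be seen, and CCNE2 ended at 5.75 at 1000 nM and 24 h, where array medians were 5.03 to 5.44.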

Other observations

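The relation without NCI-H460 was added after the result was seen.

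The mitotic genes had no common direction at 24 h and 1000 nM. Their mean score was higher in breast than in melanoma lines, though the lines overlapped and the difference was not tested. The G2/M score was 0.69 ± 0.43 (SD) in 6 breast lines, with a lowest of 0.19, and -0.74 ± 0.67 (SD) in 9 melanoma lines, with a highest of 0.30. The replication score was -2.07 ± 0.32 (SD) in melanoma and -0.77 ± 0.68 (SD) in CNS lines. The ER score at 24 h was -0.50 ± 0.44 (SD) in 4 leukemia lines and 0.31 ± 0.25 (SD) in 7 renal lines. Of single genes at 24 h, EDN2 stood at 1.83 in renal lines against 0.12 elsewhere, the polyamine gene SRM at -2.07 in colon lines against -0.76, and the neutrophil protease gene PRTN3 at -2.26 in leukemia against 0.07. The effect on PRTN3 was above 0 in 1 of the 4 leukemia lines, and its 0 nM level was not compared between tissues. At 6 h IER3 stood at 0.01 in leukemia against -1.40 elsewhere (adjusted p = 0.0035), above 0 in 2 of 4 lines. The leukemia values here count the nearly alike K-562 and HL-60 as 2 lines, and chance was not excluded for the leukemia count at 6 h.

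The response size of a line at 24 h was the slope of its 1000 nM effects on the mean effects of the other lines. It had a median of 0.978 outside the lines with high ABCB1 and an SD of 0.287 over lines. It was 0.105 in NCI-ADR-RES, 0.350 in SF-295, 0.433 in NCI-H322M and 0.470 in HCC-2998. The highest ACTB 3 prime minus 5 prime signals were 4.07 in UO-31 at 100 nM and 6 h and 3.63 in OVCAR-5 at 0 nM and 2 h, against a median of 0.679. The lowest median correlation of an array with the other arrays of its own line was 0.947, for HL-60 at 1000 nM and 24 h.

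Efflux by ABCB1 was tested as a source of weak responses at 24 h. In 53 lines of low to moderate ABCB1 the level went with the response size at r = 0.04 (permutation p = 0.777, adjusted p = 0.903, rho 0.27). Of the 4 lines with high ABCB1, 1 lay below the median response, NCI-ADR-RES, which had the highest ABCB1 level of 57 lines, 11.7, and the lowest response size, so that efflux in this line stays open. At 6 h and 1000 nM the heat shock score of 52 lines of lower ABCB1 fell with the level by rank (rho -0.36, adjusted p = 0.0422), while r was -0.34 (adjusted p = 0.0615). With the 4 lines of high ABCB1 included, r at 6 h was -0.12. At 24 h their inclusion made r of the heat shock score more negative. It went from -0.18 to -0.34 at 100 nM and from -0.16 to -0.33 at 1000 nM, and r over all lines was not tested. In most of the lower lines ABCB1 lay below every array median, so their order is largely one of signal near background. The NQO1 level was tested as a source of strong responses, and r over 57 lines was -0.02 (permutation p = 0.903).

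Higher MAPK output before treatment may go with a larger fall of the list at 24 h. Over all 57 lines r was -0.51 (permutation p = 4e-05, adjusted p = 0.00028, rho -0.53). Without the melanoma lines it was -0.41 (n = 48, permutation p = 0.00418, adjusted p = 0.0146, rho -0.39), and -0.44 without the 2 farthest lines. Within the 9 melanoma lines it was -0.47 (permutation p = 0.197). A list with a higher start has more room to fall, so a floor of the signal stays open.

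The strength of the heat shock response at 6 h was tested as a source of differences in the fall of the replication genes at 24 h, and r over 56 lines was 0.03 (permutation p = 0.808). Without NCI-H460 the permutation p was 0.845.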
